A study of Homo sapiens with 10 samples.

How the data were processed

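The samples were 5 purifications, HepG2 with a control, p21 or STAT3 probe and PC-3 with a control or p21 probe, each measured on panel 1 and panel 2. Per the labels, probes were transfected into the cells, the associated RNA was taken up on streptavidin Dynabeads and isolated with TRIzol, and miRNAs were measured with Exiqon multiplex SYBR Green RT-PCR panels. The sequence and position of the probes, the instrument, the threshold setting and the analysis software are not given in the sources used here. Groups, cell lines and panels were taken from the labels.

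The deposited main table holds unnormalised Cq values, 1 well per assay, with wells without a call marked as undetermined. A lower Cq means more template, and 1 cycle was taken as 1 log2 unit, which assumes that each cycle doubles the product. The authors also deposited a table of fold changes of 729 miRNA entries per comparison. Per the file headers these are 2 to the power of minus ΔΔCt relative to a housekeeping gene that is not named. Its columns are titled as log fold changes, but the deposited values are linear fold ratios, since none is negative and they follow from the Cq values on the linear scale. Rebuilt from the Cq values, with UniSp6 of the same panel as the normaliser and any Cq above 35 or undetermined set to 35, the folds came out within 0.01 on the log2 scale for 729 of 729 p21 entries in HepG2, 640 of 729 STAT3 entries and 712 of 729 p21 entries in PC-3. The normaliser and the limit were inferred in this way from the values. The authors' deposited folds were used as an alternative and are named as such where printed.

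There were 375 miRNA assays on panel 1 and 370 on panel 2, 745 assays for 742 miRNAs, because miR-103, miR-191 and miR-423-5p are on both panels. The panels are not replicates. Assay names are those of the panels and some are older than the present nomenclature. Detection meant a Cq of at most 35. The value of an assay was its Cq with the control probe minus its Cq with the target probe, for assays detected with both. Each panel was then centred on the median over its miRNA assays detected with both probes. A centred value of at least 1 log2 unit in size (2-fold) was counted as higher or lower. For an assay detected with the target probe only, a lower bound was computed with the control at Cq 35. The same was done for the p21 against the STAT3 purification and for the control purifications of the cell lines.

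With 1 purification per condition no test between conditions was made, and the precision rests on repeated wells. Reference assays on both panels gave an SD of 0.634 cycles for a Cq (22 pairs) and 0.693 for a difference between purifications (17). The UniSp3 calibrator, in 3 wells per plate, had an SD of 1.005 cycles over 10 plates. The SDs between panels hold well-to-well error together with offsets between panels, which centring per panel removes. For p21 in PC-3, U6 moved by 2.01 cycles on panel 1 and 0.98 on panel 2. SNORD38B, SNORD49A and UniSp6 differed between panels in the same direction. On each panel the same UniSp3 well gave the highest Cq in every purification, so its SD is not random error alone. The error of transfection or purification is not covered and is unknown. Near Cq 35 few template molecules are present, so values there are less precise than these SDs.

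Lists of miRNAs were fixed before the data were examined: the miR-17 and let-7 families, the family of miR-302, miR-372 and miR-520, other reported regulators of p21 and of STAT3, liver-enriched miRNAs, miR-221, miR-222 and miR-31, and blood-cell, muscle, neural and stromal miRNAs. The median of a list with at least 3 members was placed among 10000 random lists matched in size and in 3 classes of mean Cq. The miRNAs named were fixed by rule at the same time: the 10 highest and 5 lowest centred values per probe against its control, the 5 lowest Cq among assays detected with the target probe only, the 5 highest and 5 lowest for p21 against STAT3, the 5 with the highest lower value in both cell lines, the listed families and the reference assays. In PC-3 the 10 highest are all 10 assays measured with both probes. The 5 highest and lowest of the control comparison follow the same form of rule but were added after the data were examined. Correlations are across miRNAs. For the shared HepG2 control, 1000 simulated sets of unchanged probes were drawn with the SD of repeated wells.

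The calculation was tested on a single simulated set per comparison, with a known change of 4 log2 units and a noise SD of 0.5 cycles, below the measured one. In each, 100% of raised assays were called, which a change so far above the 2-fold size made near certain. Called too were 1.06% of 94 unchanged assays for p21 and 5.32% of 94 for STAT3 in HepG2, and 16.7% of 12 for p21 in PC-3. With so few assays these rates do not tell the comparisons apart. With the measured SD of 0.693 for a difference (200 draws, run after the data were examined), 14.8%, 14.5% and 13.8% of unchanged assays were called. That SD also holds offsets between panels. Alternatives planned before the data were examined were no centring, centring on the reference assays, on UniSp3, 1 centre for both panels, limits of Cq 37 and 32, undetected assays at the limit, 4-fold in place of 2-fold, each panel alone and the authors' deposited folds. Centring on UniSp6 with undetected assays at the limit, and on U6, SNORD38B and SNORD49A, was added afterwards, as were the lower bounds under other centres. Whether enriched miRNAs have seed matches in the p21 or STAT3 mRNA was not analysed here, since no sequence of either was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.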

Results

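MicroRNAs recovered with a probe against a chosen messenger RNA were measured in HepG2, a human liver tumour line, and in PC-3, a human prostate cancer line. A nucleic acid probe against the p21 mRNA, which encodes a cyclin-dependent kinase inhibitor, or against the STAT3 mRNA, which encodes a cytokine-activated transcription factor, was put into living cells. Material held by the probe was pulled out on streptavidin beads, a procedure the submitters call miRIP. HepG2 was purified with a control, a p21 and a STAT3 probe, and PC-3 with a control and a p21 probe. That gave 5 purifications, each run on 2 quantitative PCR panels (10 samples) with different miRNA assays, 745 assays in all. Each condition was purified 1 time, so differences had no replicate check and no p-value is given. The only error available was technical: an assay present on both panels gave differences between purifications with an SD of 0.69 cycles, offsets between panels included. The amount of p21 or STAT3 mRNA recovered was not analysed here.

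More miRNAs were detected with the target probes than with the control probe, and far more in HepG2 than in PC-3. With a Cq (the PCR cycle at which signal crosses threshold, lower for more RNA) of at most 35 counted as detected, HepG2 gave 125 of 745 assays with the control probe, 211 with the p21 probe and 256 with the STAT3 probe. PC-3 gave 16 and 53 with the control and p21 probes. There were 89 assays detected in all 3 HepG2 purifications, 10 in both PC-3 purifications and 9 in all 5, while 416 were detected in none. The median Cq of detected assays lay between 32.99 and 34.18 in the 5 purifications, close to the limit, so most of these miRNAs were scarce. None of the 45 water wells gave a Cq. The counts depended on the limit: at Cq 32 they were 30, 65 and 50 in HepG2 and 3 and 10 in PC-3, with the order of the p21 and STAT3 purifications exchanged.

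The control purifications themselves differed by cell line. Only 10 assays were detected in both, 115 in HepG2 alone and 6 in PC-3 alone. Among the 10, miR-1979 was 4.44 log2 units higher in HepG2 after centring, miR-1974 was 1.92 higher and miR-720 was 1.87 higher; these 3 names have since been withdrawn from miRBase as fragments of other small RNAs. miR-346 (-2.18) and miR-1266 (-1.28) were lower in HepG2. Without centring, 6 of the 10 were at least 2-fold higher in HepG2 and 0 lower. U6, a spliceosomal RNA, and the small nucleolar RNAs SNORD38B and SNORD49A differed by a mean of 0.23 ± 0.59 cycles (SD, 6 wells). SNORD49A was 0.96 cycles higher in HepG2, with U6 at -0.17 and SNORD38B at -0.09 (means of both panels), and UniSp6, a synthetic RNA added to the reaction, was 0.94 cycles higher in HepG2 (1.33 on panel 1 and 0.56 on panel 2).

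The p21 probe in HepG2 brought down miR-92a and its seed-sharing relative miR-92b more than any other miRNA measured with both probes. miR-92a was detected at Cq 30.58 with the control probe and 21.54 with the p21 probe, which was 7.74 log2 units above the shift of the panel (214-fold), and miR-92b was 6.41 above it (85.1-fold). These sizes depended on the centre: from the reference assays to UniSp3 alone miR-92a ran from 5.32 to 11.32 and miR-92b from 3.99 to 9.99. miR-193b (5.41), miR-320b (4.44), miR-423-5p (4.41), miR-103 (4.29 on panel 1, but 2.26 on panel 2) and miR-320a (4.26) followed. let-7b (3.97), let-7e (3.35) and let-7d (3.31), members of a family known to restrain growth genes, completed the 10 highest. Of 103 assays detected with both probes, 39 were at least 2-fold higher and 38 at least 2-fold lower than the panel median, and the 10 highest kept a positive sign under every centring tried, with let-7e and let-7d at 0.92 and 0.89 on the reference assays.

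A further 108 assays passed the limit with the p21 probe only and 22 with the control probe only. The most abundant of the 108 was miR-296-5p, at Cq 27.73 with the p21 probe, at least 62.6-fold above the control at the limit after centring. miR-423-5p on panel 2 was at least 46.7-fold higher, miR-1247 at least 16.3-fold, miR-31 at least 9.98-fold and miR-886-5p at least 7.69-fold. On the reference assays the 5 bounds fell to 11.7, 14.8, 5.18, 1.86 and 1.44. The panel 1 assay of miR-423-5p was detected with the control probe at Cq 34.43 and was 21.3-fold higher, below its panel 2 bound of 46.7. miR-886-5p is another name since withdrawn, as part of a vault-like RNA.

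**Figure D1:**
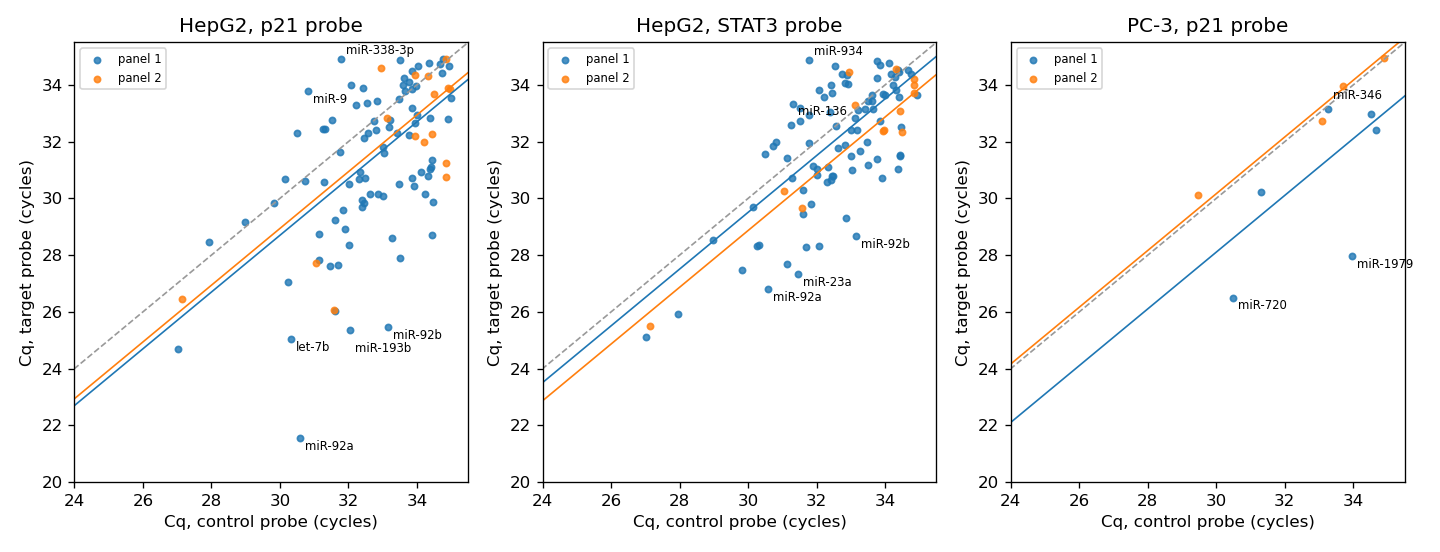
Cq with the target probe (vertical, cycles) against Cq with the control probe (horizontal, cycles) for assays detected with both, 1 point per assay, coloured by panel, in HepG2 with the p21 probe (103 assays), HepG2 with the STAT3 probe (100) and PC-3 with the p21 probe (10). The dashed line marks equal Cq and the solid lines the median shift of each panel; miR-92a lies farthest below the lines in HepG2 with the p21 probe, at 30.58 and 21.54.

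The members of the let-7 family shifted by unequal amounts under the p21 probe. Of 7 members detected with both probes, let-7b, let-7c (2.77), let-7d, let-7e and let-7g (2.01) were at least 2-fold above the panel median, let-7i was below it at the 2-fold limit (-1.03) and let-7a lay between (-0.63). Without centring all 7 were higher, from 0.27 (let-7i) to 5.28 (let-7b). let-7f was detected with the control probe only. The family's median was 2.77, at the 99.6th percentile of 10000 random lists of equal size and similar Cq. It stayed above 0 under each centring, from 0.35 on the reference assays to 6.35 on the UniSp3 calibrator. The members differ by few bases, and how well the assays keep them apart is not given in the sources used here; the same holds for miR-92a and miR-92b and for miR-320a and miR-320b.

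The miR-17 family, whose members are reported to repress p21, was higher in 3 of 4 members detected with both probes, with a median of 1.47 (80.2th percentile). That direction turned to -0.95 when the values were centred on the reference assays, some of which were themselves among the highest with this probe. On U6, SNORD38B and SNORD49A alone the median stayed positive, at 0.33. Of 11 members of the miR-302, miR-372 and miR-520 family, also reported p21 regulators, 0 were detected in any purification. Other reported p21 regulators gave 1 of 3 members at least 2-fold higher, with a median of -0.17 (32.3th percentile) that turned to 1.13 without centring, and miR-345 and miR-654-3p were detected with the p21 probe only. Reported STAT3 regulators split into 2 higher and 3 lower of 7 (median -0.63, 22.0th percentile, and 0.67 without centring).

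Lower with the p21 probe, relative to the panel, were miRNAs known from nerve and muscle. Among assays detected with both probes, miR-338-3p (-4.42), miR-9 (-4.25) and miR-128 (-3.22), all abundant in brain, were the 3 lowest. The muscle miRNA miR-133b (-3.11) and the smooth-muscle and stromal miRNA miR-143 (-2.76) followed. The 22 assays detected with the control probe only are outside this ranking. In the authors' deposited folds, with undetected assays at the limit, miR-934 stood at 0.091 and the lowest entry at 0.076, below miR-338-3p at 0.098. All 4 neural list members detected with both probes were at least 2-fold below the panel (median -2.67, 0.18th percentile), and their uncentred median was -1.37. All 3 blood-cell members (median -1.96, 5.86th percentile) and both muscle members (median -2.14) were lower too, though 1 of the muscle members was 0.13 higher without centring. The 3 stromal members gave 1 higher and 2 lower (median -1.20, 20.5th percentile, and 0.10 without centring). With the UniSp3 calibrator as the only correction the neural, blood-cell and stromal medians became 0.91, 1.62 and 2.38 and miR-133b 0.47, with miR-338-3p and miR-9 at -0.84 and -0.67; the 3 UniSp3 wells of the p21 purification on panel 1 themselves ranged from Cq 21.6 to 24.91.

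The split between higher and lower miRNAs depended on the reference. Assays detected with both probes had a median shift of 1.30 cycles on panel 1 (87 assays) and 1.06 on panel 2 (16) towards the p21 probe. Without centring 56 were at least 2-fold higher and 11 lower. Centred on the reference assays (miR-103, miR-191, miR-423-5p, U6, SNORD38B and SNORD49A) the split was 9 and 70, and with UniSp3 alone 88 and 1. On panel 1 the reference centre included miR-103 (uncentred 5.59) and miR-423-5p (5.71), which were themselves among the highest. U6 (1.86), SNORD38B (2.82) and SNORD49A (2.63) shifted less, and centred on these alone the split was 18 and 54. The authors' deposited table, which is scaled on the UniSp6 spike-in as far as its values show, lists miR-92a at 447-fold, miR-92b at 178-fold and miR-296-5p at 131-fold for this comparison.

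The STAT3 probe in HepG2 also brought down miR-92b and miR-92a, with smaller shifts, beside a group that did not lead the p21 ranking. That group was miR-23a, miR-423-3p, miR-30c, miR-125a-5p, miR-15b and miR-484. In the authors' deposited folds it was higher with the p21 probe too, from 4.49-fold (miR-30c) to 13.8-fold (miR-125a-5p). miR-92b was 4.02 log2 units above the panel (16.2-fold), miR-23a 3.64, miR-92a 3.30 and miR-193b 3.24. miR-423-3p (3.07), miR-30c (2.95), miR-125a-5p (2.91), miR-15b (2.83), miR-484 (2.69) and miR-423-5p (2.46) followed. On the reference assays these 10 ran from 2.40 (miR-92b) to 0.85 (miR-423-5p, under 2-fold), and with UniSp3 alone from 5.81 to 4.25. Lowest were miR-934 (-3.59), miR-412 (-2.62), miR-219-5p (-2.61), miR-136 (-2.50) and miR-128 (-2.23), of which miR-219-5p and miR-128 are brain miRNAs. With UniSp3 alone miR-219-5p (-0.82), miR-136 (-0.71) and miR-128 (-0.44) fell short of 2-fold, while miR-934 (-1.80) and miR-412 (-1.39) did not. Of 100 assays detected with both probes, 29 were at least 2-fold higher and 25 lower. There were 156 assays detected with the STAT3 probe only, led by miR-423-5p on panel 2 (at least 13.5-fold), miR-197 (10.2-fold), miR-365 (9.57-fold), miR-191 on panel 2 (6.0-fold) and miR-31 (5.69-fold), and 25 with the control probe only. On the reference assays these bounds fell to 7.75, 3.32, 3.12, 3.45 and 1.86. The panel 1 assay of miR-423-5p, detected with the control probe, was 5.51-fold higher, below its panel 2 bound of 13.5.

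The reported STAT3 regulators were 2 higher, 1 lower and 2 between, with a median of 0.70 (47.6th percentile) that turned to -0.91 on the reference assays. The let-7 family had a median of -0.26 (37.6th percentile) with 3 of 7 members at least 2-fold higher, and its sign turned to 0.23 without centring. The miR-17 family had 2 of 3 members higher (median 1.02, 58.0th percentile), which turned to -0.59 with the reference assays as the centre, and the other reported p21 regulators 1 of 3 (median 0.29, 41.2th percentile, and -1.32 with that centre). Of the neural list, 3 of 5 members were at least 2-fold lower (median -1.67, 0.93th percentile). Blood-cell and muscle lists each had 2 of 3 members lower, with medians of -1.71 (11.0th percentile) and -1.56 (9.30th percentile), and both stromal members were lower (median -1.39). With UniSp3 alone the neural, blood-cell and muscle medians became 0.12, 0.08 and 0.23. Of 6 liver-enriched miRNAs, 4 (miR-148a, miR-192, miR-194 and miR-215) were detected with the STAT3 probe only, the lowest at Cq 33.67, and 0 with the control or p21 probe in either line.

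Medians of the assays detected with both probes moved by 0.49 cycles on panel 1 (87 assays) and 1.13 on panel 2 (13) towards the STAT3 probe. Without centring the split was 41 higher and 20 lower, with the reference assays 9 and 59, and with UniSp3 alone 71 and 2. In the authors' deposited table miR-92b stands highest for STAT3, at 31.9-fold.

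Set directly against the STAT3 purification, the p21 purification held more miR-92a, miR-296-5p and let-7, and less miR-1979 and miR-125b. This comparison made no use of the control, but it set 1 purification against 1 other, and U6, SNORD38B and SNORD49A were a mean of 0.44 cycles higher in the p21 purification. miR-92a was 4.61 log2 units higher with the p21 probe (24.4-fold), miR-296-5p 4.56, miR-320b 3.52, miR-199a-5p 3.23 and let-7c 3.20. Lower were miR-1979 (-3.19), miR-125b (-3.00), a reported STAT3 regulator, miR-338-3p (-2.60), miR-9 (-2.41) and miR-197 (-2.39). From the reference assays to UniSp3 alone miR-92a ran from 3.59 to 6.23 and miR-1979 from -4.21 to -1.57, and with UniSp3 alone the last 3 fell short of 2-fold (-0.98, -0.79 and -0.77). Of 6 let-7 members measured with both probes, 5 were at least 2-fold higher with p21 (median 2.55, 99.4th percentile), with medians from 1.53 to 4.17 under the other centrings. Reported STAT3 regulators were 1 higher and 2 lower of 5 (median -0.67, 8.75th percentile), which turned to 0.51 at Cq 37 and 1.12 with undetected assays at the limit. Neural members were 2 lower of 4 (median -1.05, 4.76th percentile), which became 0.57 with UniSp3 alone. The miR-17 family had 1 of 3 members higher (median 0.79, 60.3th percentile, and -0.23 on the reference assays), and other reported p21 regulators 1 of 3 lower (median -0.75, 13.3th percentile, and 0.21 at Cq 37).

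Of 155 assays detected with both target probes, 45 were at least 2-fold higher with p21 and 31 with STAT3, while 56 were detected with p21 only and 101 with STAT3 only. Without centring the split was 58 and 17, with the reference assays 26 and 76, and with UniSp3 alone 85 and 14.

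The p21 and STAT3 enrichments were correlated across miRNAs, with a control purification in common. Over the 89 assays detected in all 3 HepG2 purifications, Pearson's r was 0.71 and Spearman's rho 0.67, across miRNAs that are not independent replicates. Of these, 21 were at least 2-fold higher with both probes, where independent lists would share 12.4, and 16 were lower with both, where 6.74 would be shared. Unchanged probes simulated against the same control, with the error of repeated wells only, gave an r of 0.50 and 4.29 assays higher in both. That r follows from equal error in all purifications, whatever its size, and so is not a measured baseline. The count of 4.29 does depend on that size, and the SD used also holds offsets between panels. The error of the control purification itself enters both enrichments and was not part of the simulation, and the control could not be split, so how much of the correlation comes from it is open. Assays higher with both included miR-92a, miR-92b, miR-193b and miR-423-5p.

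**Figure D2:**
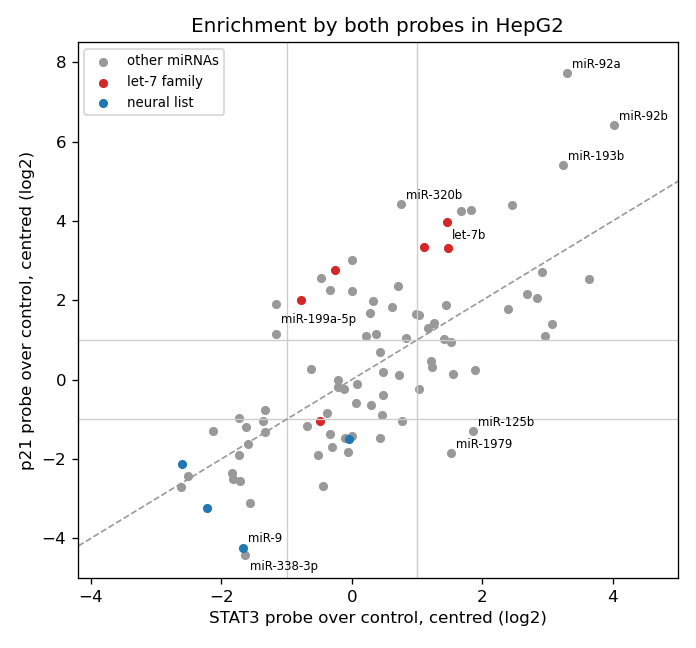
Centred enrichment over the control probe with the p21 probe (vertical, log2) against that with the STAT3 probe (horizontal, log2) in HepG2, 1 point per assay detected in all 3 purifications (89). Grey lines mark 2-fold and the dashed line equal enrichment; let-7b, let-7c, let-7d, let-7e and let-7g lie above the dashed line, and miR-9, at -4.25 for p21, lies at the lower left.

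In PC-3 the p21 probe recovered miRNAs that the control probe did not bring above the limit, again with miR-92a first. miR-92a gave no Cq with the control probe and 27.81 with the p21 probe, at least 39.3-fold higher after centring. let-7b was at least 17.4-fold higher, miR-320a 6.78-fold, miR-940 6.05-fold and miR-92b 4.69-fold (33.3, 14.7, 5.74, 5.12 and 3.97 on the reference assays). They belonged to 43 assays detected with the p21 probe only, against 6 with the control probe only. Among the 10 assays detected with both, miR-1979 (4.11) and miR-720 (2.09) were at least 2-fold higher and miR-346 (-1.77) lower. The other 7, miR-1266, miR-663, miR-485-3p, miR-520h, miR-324-3p, miR-1974 and let-7d*, lay between 0.51 and -0.82. The centre rested on 6 assays on panel 1 (1.89 cycles) and 4 on panel 2 (-0.16), and without it 5 were higher and 0 lower, with miR-346 at 0.12. Centred on the reference assays the split was 2 and 5, and with UniSp3 alone 5 and 0.

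Of the fixed lists in PC-3, the let-7 family had 3 members detected with the p21 probe only, miR-221 and miR-222 (abundant in PC-3) were 2 more, and the miR-17 family had 1. The other reported p21 regulators had miR-423-3p detected with the p21 probe only and miR-663 at 0.37 with both. Among reported STAT3 regulators, 1 was detected with the p21 probe only. Its Cq, 34.33, was that of the miR-17 family member, so the lists appear to share this assay. Neural, muscle, blood-cell, stromal and liver-enriched miRNAs gave 0 detected assays in either PC-3 purification.

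The p21 probe could be compared between the cell lines for only 9 assays detected in all 4 purifications, which excluded miR-92a and let-7b. Across these 9 miRNAs r was 0.10 and rho 0.02, and only miR-720 was at least 2-fold higher in both (1.03 in HepG2 and 2.09 in PC-3), against 0.222 for independent lists. The next were miR-1974 (-0.40 and -0.48), miR-663 (-0.63 and 0.37), miR-520h (-0.77 and -0.11) and miR-324-3p (-0.88 and -0.37). The miR-720 call in HepG2 depended on the centre. Its uncentred 2.33 was above the panel 1 shift of U6 (1.86) but below those of SNORD38B (2.82), SNORD49A (2.63), miR-103 (5.59) and miR-423-5p (5.71). A comparison chosen after the data were examined set undetected assays to Cq 35 and used UniSp6 as the centre, which admitted 50 assays. Of these, 14 were at least 2-fold higher in both lines, against 11.2 for independent lists, and r was 0.47. Highest in both were miR-92a (447-fold in HepG2 and at least 104-fold in PC-3), let-7b (32.9 and at least 45.8), miR-320a (40.1 and at least 17.9), miR-92b (178 and at least 12.4) and let-7e (21.3 and at least 11.1). On the same scale the 5 were also higher with the STAT3 probe in HepG2, from 4.24-fold (let-7e) and 5.44-fold (let-7b) to 31.9-fold (miR-92b). The reference RNAs rise on that scale too. Uncentred on panel 1 with the STAT3 probe, UniSp6 moved by -0.49 cycles, and U6, SNORD38B and SNORD49A by 1.44, 1.90 and 1.91. The rises of let-7e and let-7b with the STAT3 probe were therefore comparable to those of the references.

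The reference RNAs were not constant between purifications. U6, SNORD38B and SNORD49A were higher with each target probe than with its control in 6 of 6 wells. The mean shift was 2.47 ± 0.54 cycles for p21 in HepG2 (SD, 6 wells), 2.03 ± 0.40 for STAT3 in HepG2 and 1.65 ± 0.57 for p21 in PC-3. UniSp6 moved far less on average, by 0.30, 0.17 and -0.05 cycles in the same order, but it was not constant on single panels. It moved by 0.24 cycles on panel 1 and 0.36 on panel 2 for p21 in HepG2. For STAT3 it moved by -0.49 and 0.82, and for p21 in PC-3 by 0.49 and -0.59. The enrichment values are relative to the median of each panel, not to these RNAs.

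**Figure D3:**
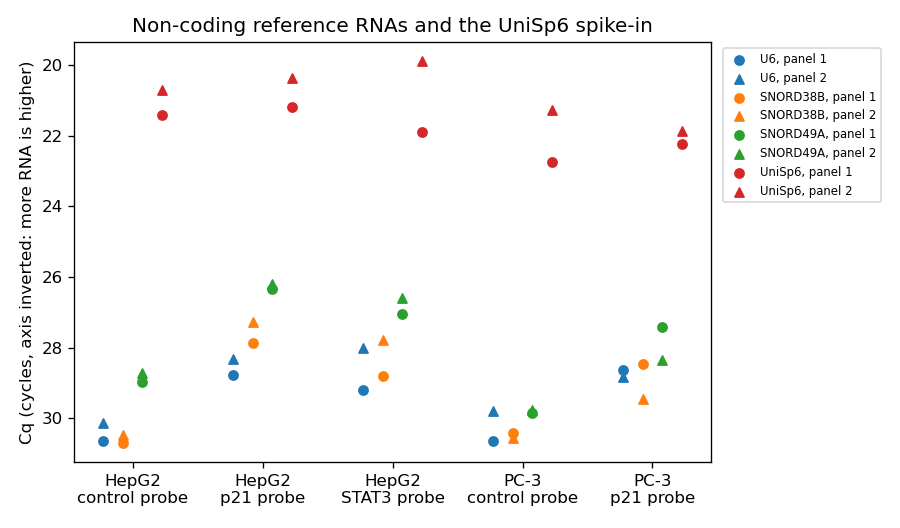
Cq (vertical, cycles, inverted so that more RNA is higher) of U6, SNORD38B, SNORD49A and the UniSp6 spike-in in each of the 5 purifications, 1 well per panel (circles panel 1, triangles panel 2). The 3 non-coding RNAs lie higher with the p21 and STAT3 probes than with the control probes, by 2.47, 2.03 and 1.65 cycles on average.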

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

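The tests in this part were chosen after the results were seen, except the recalculations of miR-1266 in PC-3 without centring, on the reference assays and with 1 centre for both panels. The reference RNAs drew attention because they lie outside the miRNA measurement and were higher than in the control purifications. In HepG2 with the p21 probe, U6 was 1.84 cycles higher than with the control probe, SNORD38B 3.0 and SNORD49A 2.58 (means of both panels). With the STAT3 probe they were 1.78, 2.29 and 2.03 higher, and in PC-3 with the p21 probe 1.5, 1.53 and 1.92.

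A larger yield of every small RNA in the target purifications would raise all miRNAs by about as much. In HepG2 it did not: the nerve, muscle, blood-cell and stromal miRNAs detected with both probes had an uncentred median of -0.74 with the p21 probe (12 assays, quartiles -1.55 and -0.11) and -1.12 with the STAT3 probe (13 assays, quartiles -1.24 and -0.20), against reference means of 2.47 ± 0.54 and 2.03 ± 0.40. The neural list was already known to be among the lowest (0.18th percentile with p21 and 0.93th with STAT3). The failure of these lists to rise is therefore not an independent test. Over all assays detected with both probes, the median shifts on panels 1 and 2 were 1.30 and 1.06 cycles for p21 and 0.49 and 1.13 for STAT3. The miRNAs detected with both probes in HepG2 thus did not rise as a whole by as much as the references. Assays detected with 1 probe only are outside these medians. On panel 2 there were 67 with the p21 probe only against 1 with the control probe only, and 104 against 4 for STAT3. Whether panel 2 as a whole rose by as much as the references cannot be told from these medians. RNA that entered after the capture step would not follow a uniform gain, and that was not tested. In PC-3 the number of nerve, muscle, blood-cell and stromal miRNAs detected with both probes was 0, so a uniform gain there cannot be told apart from a selective one. A control purification that was itself poor in these RNAs also stays open, since there was 1 control purification per cell line. A biological difference, such as small nuclear and nucleolar RNAs held with the probed mRNA, stays open and was not tested.

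The second pattern was the presence of miRNAs of other tissues in HepG2 and not in PC-3. Of 24 assays on the nerve, muscle, blood-cell and stromal lists, 16 were detected in at least 1 HepG2 purification and 10 in all 3, with miR-124 lowest at Cq 28.52 to 29.16. The number detected in PC-3 was 0, which was not particular to these lists. The PC-3 control and p21 purifications detected 2.15% and 7.11% of all 745 assays, and the let-7 family had 8 of 9 members in the HepG2 control and 0 in the PC-3 control. The reported STAT3 regulators had 7 and 0, but that list appears to overlap the other-tissue lists. Its lowest Cq in the HepG2 control, 28.97, is that of the neural list. The absence of the same 24 assays in PC-3 argues against amplification without template, which would not depend on the cells. A lower yield of every small RNA in PC-3 is argued against as well: U6, SNORD38B and SNORD49A differed between the control purifications by 0.23 ± 0.59 cycles, at most 1.03 higher in HepG2 in a single well, while the 5 neural miRNAs of the HepG2 control fell short in PC-3 by a median of at least 2.92 cycles. A lower yield of miRNAs as a class in PC-3, with U6 and the SNORDs unaffected, stays open and was not tested. RNA from other tissues and the expression of HepG2 itself cannot be told apart, because 0 samples of HepG2 RNA before capture were analysed here.

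The third pattern concerns the authors' deposited table. From miR-191* to miR-1979 in the PC-3 column, 23 of 23 successive values equal, within 0.01 on the log2 scale, the fold rebuilt for the miRNA in the row above, and 17 of them are not the fold of the miRNA they stand beside. Most folds in this stretch are background values shared by many rows, but miR-1914, miR-193b and miR-1972 have folds of their own, and these stand beside miR-1914*, miR-193b* and miR-1979. A candidate explanation is that names and values moved by 1 row against each other. In that reading miR-1979 in PC-3 is listed at 1.91-fold and rebuilt at 45.7-fold, and miR-193b is listed at 0.710-fold and rebuilt at 1.79-fold. In the STAT3 column 89 folds were not rebuilt with the limit, and all 89 follow, within 0.02 on the log2 scale, from the STAT3 Cq as measured, up to 37.25, in place of 35. A Cq above 35 in other rows of that column was set to 35, and why these 89 differ was not tested.

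Effects of the p21 probe with opposite signs in the cell lines, centred and uncentred, were seen for 2 of the 9 miRNAs measured in both, and the difference was not tested. miR-1979 was -1.84 in HepG2 and 4.11 in PC-3, and miR-1266 was -1.46 in HepG2 and 0.51 in PC-3. The opposite signs depended on the centre. miR-1266 in PC-3 became -0.82 on the reference assays, -0.82 on U6 with the SNORDs and -0.36 with 1 centre for both panels, and its uncentred values, -0.40 in HepG2 and 0.35 in PC-3, lay within the technical SD of 0.69 cycles of 0. miR-1979 in HepG2 became 1.74 with UniSp3 alone, and its p21 effect was 3.87 to 8.13 log2 units larger in PC-3 than in HepG2 under every centring tried. Its Cq with the p21 probe was similar in HepG2 (28.48) and PC-3 (27.97), while the control wells stood at 27.94 and 33.97. The difference thus rests mainly on 1 control well per line.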

How the results depend on the processing

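Centring on UniSp6 with undetected assays at the limit, centring on U6 with the SNORDs, and all changes of centre for the lists other than none were chosen after seeing the data. No paired analysis was possible because each condition had 1 purification. The seed-site analysis was not run, since no genome was used, and Cq 32 left 3 assays for PC-3 p21 over control, for the controls and for the cell line comparison, too few to centre, as did panel 2 alone for the last. Named miRNAs with a centred value of at least 1 in size kept their sign in 394 of 398 recalculations, and those under 1 in 44 of 72. The former were named for extreme values, and most recalculations only subtract a constant per panel, so most of their signs were bound to stay. The deposited folds also largely repeat the UniSp6 setting. The exceptions among those of at least 1 in size were miR-128, miR-133b and miR-143 with p21 in HepG2, at 0.36, 0.47 and 0.82 with UniSp3 alone, and miR-346 in PC-3, at 0.12 without centring. Except where a limit, panel or fold size itself sets how many assays enter, or a new centre shifts every value alike, the cause was not tested.

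Counts below are miRNAs at least 2-fold higher and lower. For p21 over control in HepG2 (39 and 38), 11 were lower without centring. Reference assays gave 9 and 70, UniSp3 88 and 1, Cq 32 6 and 8, UniSp6 97 and 25, 4-fold 21 and 12, panel 2 alone 6 and 4, and the authors' deposited folds gave 94 and 25. Counts higher were 64 at Cq 37, 74 with undetected at the limit and 18 on U6 with the SNORDs. For STAT3 (29 and 25), reference assays gave 9 and 59, UniSp3 71 and 2, Cq 37 48 and 49, Cq 32 4 and 9, undetected at the limit 55 and 38, UniSp6 80 and 15, U6 with the SNORDs 11 and 54, 4-fold 11 and 8, panel 2 alone 1 and 3, and the deposited folds gave 77 and 60. Those folds hold 89 values from a STAT3 Cq above 35 left as measured. The UniSp6 count of 15 lower has the limit applied to every assay.

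For p21 in PC-3 (2 and 1), no centring and UniSp3 each gave 5 and 0, Cq 37 9 and 5, undetected at the limit 16 and 4, UniSp6 18 and 2, panel 2 alone 0 and 0, and the deposited folds gave 17 and 2. Counts lower were 5 on the reference assays, 5 on U6 with the SNORDs and 0 at 4-fold. For p21 against STAT3 (45 and 31), 17 were lower without centring. Reference assays gave 26 and 76, UniSp3 85 and 14, Cq 37 85 and 77, Cq 32 12 and 9, undetected at the limit 76 and 52, UniSp6 72 and 66, 4-fold 26 and 7, and panel 2 alone 16 and 8. Panel 1 alone gave 29 higher. For the controls, HepG2 over PC-3 (3 and 2), no centring gave 6 and 0 and Cq 37 12 and 9.

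For p21 in both lines, r of 0.10 became 0.31 at Cq 37 with 4 higher in both, and 0.47 with UniSp6 with 14. For p21 with STAT3, r of 0.71 became 0.54 at Cq 32. The 21 higher in both became 35 without centring, 35 at Cq 37, 3 at Cq 32 and 55 with UniSp6. Detected assays at Cq 37 were 209 for the HepG2 control, 453 for STAT3, 57 for the PC-3 control and 114 for PC-3 p21. At Cq 32 they were 30, 65 and 50 for HepG2 control, p21 and STAT3, and 3 and 10 for PC-3.

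List medians of at least 1 in size changed sign in 11 of 106 recalculations, and those under 1 in 27 of 82. Among the former, with UniSp3 alone, were the p21 blood-cell (1.62), neural (0.91) and stromal (2.38) lists, the STAT3 blood-cell (0.082), muscle (0.23) and neural (0.12) lists, and the neural list for p21 against STAT3 (0.57). The p21 stromal list changed to 0.10 without centring. The miR-17 family changed to -0.95 (p21) and -0.59 (STAT3) on the reference assays and to -0.24 (STAT3) on U6 with the SNORDs. For p21 it kept its sign on U6 with the SNORDs, at 0.33. Few template molecules near Cq 35 limit what single assays can show.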

Other observations

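The liver-enriched miRNAs miR-148a, miR-192, miR-194 and miR-215, detected in HepG2 with the STAT3 probe at Cq 34.41, 33.76, 34.43 and 33.67, gave 0 detected assays with the control or p21 probe in HepG2, where miR-148a stood at Cq 37.55 and 37.62. They were no lower than Cq 37.82 in PC-3 where a Cq was given. miR-122, the most abundant miRNA of liver tissue, gave no Cq in any purification. The STAT3 purification also had the most assays at Cq 37 or below, 453 of 745, and 101 assays that passed Cq 35 there and not with the p21 probe.

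Some miRNAs moved apart from their closest relatives. With the p21 probe in HepG2, let-7g went from Cq 31.15 to 27.83 and let-7c from 34.24 to 30.16, while let-7i went from 32.57 to 32.30 and let-7a from 33.85 to 33.18. miR-125b stayed at Cq 29.83 with the control and p21 probes and reached 27.48 with the STAT3 probe. The strands of let-7d also parted, let-7d by 4.61 cycles towards the p21 probe and let-7d* by -0.53. miR-199a-5p was 3.20 cycles higher with the p21 probe, while miR-199a-3p was above the limit in all 3 HepG2 purifications.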
